A study of Mus musculus with 3 samples.

How the data were processed

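Total RNA was isolated with a Qiagen column kit and libraries were made by the Illumina TruSeq protocol, per the labels' protocols. The 3 libraries are of CD34-KSL cells cultured for 24 h in complete, valine-deficient and cysteine-deficient medium, and each sample's group was taken from the culture medium its label names. There is 1 library per medium. Reads were aligned to the mm9 build with TopHat2 and expression was estimated with Cufflinks 2.1.1, per the submitters' processing notes. Options of these programs, the gene annotation, read length, trimming and the use of strand are not given in the sources used here. The values the authors deposited are FPKM, fragment counts scaled for transcript length and for the number of mapped fragments, for 23234 gene symbols per library, and no symbol was repeated. Cufflinks is known to divide fragments among overlapping and near-identical genes by an estimate, so values of close copies (globins, histones, class I genes, ribosomal proteins with processed copies) are uncertain, and a value of 0 is reported only as listed at 0. Values at or under 0.001 FPKM are treated as listed at 0, which covers 41, 48 and 41 values above 0 in the complete, valine-deficient and cysteine-deficient libraries. Without strand, fragments of a gene and of an overlapping gene on the other strand cannot be told apart.

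Depth is not given in the files, but it can be read from the steps of low values. For 15356 genes with 1 RefSeq transcript, lengths were taken from GENCODE release M21, which uses another genome build (GRCm38) than the files, so only names and lengths were used and no coordinates are given. In all, 20841 of the 23234 symbols were found there. The size of the steps and a length offset of 180 bases were fitted on low FPKM values of genes between 1500 and 8000 bases. Low values of genes of known length were then multiplied by the transcript length less 180 bases. They sat within 0.1 of whole multiples of 1 value for 58.1%, 58.5% and 55.9% of low genes in the complete, valine-deficient and cysteine-deficient libraries. By chance 20% is expected, which does not allow for the fit on overlapping values. A fragment on 1 kb of transcript was thus worth 0.481, 0.468 and 0.450 FPKM. Ratios of low genes between libraries gave the valine-deficient library as 3.43% and the cysteine-deficient library as 7.47% deeper than the complete-medium library. These steps give estimated fragments per gene, with a median of about 58.0 per tested gene of known length in the comparison of valine-deficient with complete medium. Exact Clopper-Pearson 95% intervals of the ratio of 2 libraries were computed from them. The fragments were counted without molecular identifiers, so the intervals cover counting error only, and neither they nor the FPKM values say how much cultures in 1 medium vary.

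With 1 library per medium no test was made and no p-value is given. The log2 ratio was log2((FPKM + 1)/(FPKM + 1)) of the deposited values. Genes with a mean of at least 1 FPKM over the 3 libraries entered (10734 genes), and a gene was counted as higher or lower at a ratio of at least 2. Each of 39 gene lists, fixed before the data were examined together with the size rule, the filter and the first set of alternatives, was summarised by the median log2 ratio of its members past the filter when there were at least 5 of them. The percentile of that median was taken among 10000 random lists of the same size matched on mean expression in 20 bins (2000 under the alternatives). A percentile under 2.5 or over 97.5 is called outside the central 95%, as a description of these libraries. The correlation and overlap of the 2 comparisons that share the complete-medium library were set beside 100 simulated draws of 3 unchanged libraries. Each had normal noise with the spread of the cysteine-deficient to valine-deficient ratio in its expression bin divided by the square root of 2. They were also set beside the overlap of independent lists. Named genes were chosen by a rule fixed in advance. It takes, for each comparison, the 12 highest and 12 lowest ratios among genes with a mean of at least 5 FPKM and a ratio of at least 2, leaving out unnamed models and small RNA genes, then up to 4 genes with the largest absolute ratios of each list, and 21 genes always named. Genes named outside this rule are said to be so.

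The procedure was tested on simulated fragments that held counting error only, for the comparison of valine-deficient with complete medium over 6204 genes. Of genes raised 2-fold 34.0% and of genes lowered 2-fold 42.0% passed the 2-fold rule, of genes changed 4-fold 100.0% and 92.0% passed it, all in the right direction, and of unchanged genes 1.17% passed. Among 200 unchanged lists, drawn at random from unrelated genes, 5 lay outside the central 95%. These rates do not cover variation between cultures or genes of a list that vary together. The changed genes were drawn from those with a mean of at least 5 FPKM. A true 2-fold difference lies at the cut-off itself, so many such differences are missed on any scale. How much the log2(FPKM + 1) scale adds to this was not tested. Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, scaling to the same median, upper quartile or sum, other fold thresholds, random lists not matched on expression, the mean in place of the median, and lists without members they share with others. Leaving out repeated symbols changed nothing, since there were none. Leaving out 729 small RNA genes, genes listed at 0 in any library or genes under 20 estimated fragments, and a same-sum scaling without small RNA genes, were added after the data were seen. Small RNA genes held 16.6%, 17.2% and 16.4% of the FPKM sum in the 3 libraries. They were kept in the counts (82 of them passed the filter) and left out of the named genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.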

Results

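RNA was sequenced from CD34-KSL cells of 9-week-old B6 mice, the CD34-negative fraction of lineage-negative, Kit-positive and Sca-1-positive cells in which mouse haematopoietic stem cells are found. For each culture 10000 cells were kept for 24 h with stem cell factor and thrombopoietin, the cytokines that signal through Kit and Mpl, in complete medium, in medium without valine or in medium without cysteine. Valine is an essential branched-chain amino acid, and cysteine, which mammals can make from methionine, is a building block of glutathione. There was 1 library per medium, 3 in all, so no difference has a replicate check, and every comparison below is between libraries. The deposited FPKM values carried steps that correspond to about 2080000 fragments in the complete-medium library, 2140000 in the valine-deficient library and 2220000 in the cysteine-deficient library, and 13112, 13295 and 12907 genes were above 0. Fold differences are on the log2(FPKM + 1) scale, which understates those of low genes, and counting intervals are 95% intervals of the ratio of estimated fragments that cover counting error only. The design asks how expression in each deficient medium differed from that in complete medium.

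Without valine, genes of cell division were far lower than in complete medium. Genes of the amino acid stress response, of the interferon response, of p53 and of inflammation were higher. Of 30 mitosis genes, 28 were at least 2-fold lower and none was 2-fold higher, with a median log2 ratio of -2.66. Birc5, the survivin gene of the chromosomal passenger complex, stood at 8.72 FPKM against 111 in complete medium, the kinase gene Aurkb at 5.25 against 71.7 and the cyclin B1 gene Ccnb1 at 4.14 against 47.4. Of 17 ATF4 and integrated stress response genes, 11 were at least 2-fold higher and none lower, with a median of 1.43. Trib3, a pseudokinase gene induced by ATF4, was 9.49-fold higher (116 against 11.3 FPKM, counting interval 7.42 to 14.1), and Atf4 itself was at 162 against 86.4 FPKM.

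The division genes included those of DNA synthesis. Of 32 DNA replication genes, 26 were at least 2-fold lower (median -1.31), with thymidine kinase gene Tk1 at 11.9 against 169 FPKM, a 13.2-fold difference, and the ribonucleotide reductase gene Rrm2 at 25.4 against 219 FPKM. Ccne1, the cyclin E1 gene, was at 6.79 FPKM in complete medium and listed at 0 without valine. The proliferation marker Mki67 was 4.73-fold lower, at 1.68 against 11.7 FPKM. Of 10 replication-dependent histone genes 7 were 2-fold lower and 1, Hist1h2bc, was 3.50-fold higher, with a median of -1.57. Histone genes are uncertain because near-identical copies share fragments. Of the 9 with a known transcript length, only 3 had a counting interval below 1, and 1 had an interval above 1. Among the genes with the lowest ratios at a mean of at least 5 FPKM were further division genes: Fam64a (0.365 against 25.7 FPKM), Cenpa, which encodes the centromeric histone variant (1.22 against 28.6 FPKM), the kinase gene Pbk (6.39 against 92.1 FPKM) and the condensin gene Ncapg (0.922 against 22.8 FPKM). Cdkn3 was listed at 0 in both deficient libraries and at 15.9 FPKM in complete medium.

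Within the ATF4 group the transcription factor genes Atf5 and Cebpb were 6.43-fold and 7.53-fold higher, Cebpb at 12 against 0.733 FPKM with a counting interval of 4.24 to 142. Ddit3, which encodes CHOP, was at 67.0 against 20.7 FPKM, Chac1, a glutathione-degrading enzyme gene, at 25 against 4.54, and Sesn2, whose product restrains mTORC1, at 6.76 against 1.36. The 16 biosynthetic genes driven by ATF4 did not stand apart, with a median of -0.06, 1 gene 2-fold higher and 1 lower. Asns, the asparagine synthetase gene, was at 416 against 341 FPKM, and Pycr2 was 2.13-fold lower. None of the 20 cytosolic aminoacyl-tRNA synthetase genes was 2-fold apart (median -0.05), with the valyl-tRNA synthetase gene Vars at 16.4 against 18.0 FPKM. The 26 genes of branched-chain amino acid catabolism also held no gene 2-fold apart (median -0.06), and Bcat1 was at 11.7 against 10.6 FPKM. Of 16 amino acid transporter genes, Slc1a4 and the cationic transporter gene Slc7a3 were 2-fold higher (median 0.37).

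Of 27 interferon response genes, 16 were at least 2-fold higher without valine and none was lower, with a median of 1.10. Mx1, an antiviral GTPase gene, was 8.87-fold higher (19.3 against 1.29 FPKM, counting interval 6.77 to 36.8), Ifit3 was at 133 against 27.5 FPKM, Ifit1 at 264 against 75.3 and the chemokine gene Cxcl10 at 513 against 160.0. Of the 17 members with a known transcript length, 16 had a counting interval above 1 and 1 had an interval below 1. Genes of other blood cells were higher in the same library. Of 12 neutrophil and monocyte genes 7 were 2-fold higher (median 1.12), among them Lcn2 (36.9 against 11.0 FPKM) and the granule protein gene Ngp, which was listed at 0 in complete medium and at 9.14 FPKM without valine. Of 7 macrophage and dendritic cell genes 3 were 2-fold higher (median 0.77), among them the class II genes H2-Aa (74.0 against 27.5 FPKM) and H2-Ab1 (49.4 against 24.1 FPKM).

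The 20 NF-kB and inflammatory genes had a median of 0.81, with 9 members 2-fold higher and none lower. Ccl5 was at 7156 against 2044 FPKM and Ccl4 at 1149 against 295 FPKM, both chemokine genes, and Ptgs2, which encodes cyclooxygenase, was 2.02-fold higher. Of 16 immediate early genes 5 were 2-fold higher (median 0.62), including Dusp6, Zfp36, and Atf3 at 4.68 against 0.806 FPKM. Of 23 p53 target genes 10 were 2-fold higher and 1 lower (median 0.53). Cdkn1a, the gene of the p21 inhibitor of cyclin-dependent kinases, was at 66.1 against 32.1 FPKM and Plk2 at 10.1 against 2.38, while Gtse1, a gene of the G2 and S phases, was 2.49-fold lower. The 13 CDK inhibitor and quiescence genes (median 0.38, 3 higher) included Klf6 at 39.6 against 10.9 FPKM and Txnip at 45.0 against 21.8. Of 12 BCL2 family genes 3 were higher and 1, Bcl2, was lower (median 0.37), but Bcl2a1a and Bcl2a1b, among the 3, are near-identical copies and uncertain. Of 26 autophagy and lysosome genes 3 were higher (median 0.30), including the autophagy receptor gene Sqstm1 at 102 against 35.8 FPKM and Atg14 at 8.37 against 2.93.

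Several groups were lower by less. The 30 ribosome biogenesis genes had a median of -0.48, with Cad and the ornithine decarboxylase gene Odc1 at least 2-fold lower, and the 29 nuclear genes of oxidative phosphorylation a median of -0.47, with Cox5a and Uqcrfs1 2-fold lower. The 12 cytosolic heat shock genes (median -0.51) had 1 member 2-fold lower, the chaperonin gene Hspe1, at 334.0 against 674 FPKM. The 16 genes of the methionine cycle, transsulfuration and cysteine catabolism had a median of -0.48, with Ethe1 2.1-fold lower and Cth, which encodes the transsulfuration enzyme that releases cysteine, 2.34-fold higher. Random lists of equally abundant genes were at -0.13 for ribosome biogenesis, -0.19 for oxidative phosphorylation, -0.14 for heat shock and -0.07 for the methionine cycle. The 38 haematopoietic stem cell genes had a median of 0.17, with Txnip 2-fold higher and Gfi1b 2-fold lower. The stem cell marker gene Procr was at 75.8 against 41.0 FPKM, the receptor gene Kit at 155 against 124 and Mpl at 212 against 186. Cd34 was at 65.9 against 109 FPKM. The CD34-negative label of these cells refers to the sort before culture, not to RNA after 24 h.

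Other groups lay inside the central 95% of random lists. Their medians were -0.05 for the 33 NRF2 and glutathione genes, -0.27 for the 21 genes of the unfolded protein response, -0.06 for 23 cholesterol and -0.22 for 11 fatty acid synthesis genes, -0.31 for 9 genes of D-type cyclins and MYC, -0.31 for 48 cytosolic ribosomal protein genes, -0.23 for 25 genes of glycolysis and the hypoxia response, 0.16 for 25 mTORC1 input genes, 0.19 for 19 iron and ferroptosis genes, -0.02 for 7 multipotent progenitor genes, 0.23 for 17 megakaryocyte genes, -0.03 for 8 erythroid genes, 0.31 for 5 mast cell and basophil genes and -0.19 for 17 housekeeping genes. Of the 33 NRF2 and glutathione genes 5 were still 2-fold higher and none lower. Their mean was 0.17, with 15 genes above 0 and 18 below. Of the 19 iron and ferroptosis genes 4 were 2-fold higher and none lower. Ccnd1, the cyclin D1 gene, was 2.22-fold lower at 1.54 against 4.64 FPKM, while Myc was at 223 against 210 FPKM. Actb was at 10050.5 against 8607 FPKM and Gapdh at 709 against 1264. Only 3 lymphocyte and 4 endothelial and stromal genes passed the filter, too few for a median, and the symbols of mitochondrially encoded genes were not analysed here.

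In total 1312 of 10734 genes with a mean of at least 1 FPKM (12.2%) were at least 2-fold apart, 629 higher and 683 lower without valine, and 76 and 150 were at least 4-fold higher and lower. Among the 6194 of them with a known transcript length, 764 were 2-fold apart where counting error alone gave 81.8. The groups named as higher or lower are the 19 of 36 lists whose median lay outside the central 95% of random lists matched on expression. Lists of unrelated genes would give 1.8. Members of a real list can vary together between single cultures, and some lists share members, so 1.8 does not measure chance between cultures. The calls for amino acid transporters, heat shock, methionine cycle, BCL2 family, CDK inhibitor, oxidative phosphorylation, autophagy and stem cell genes ended under at least 1 other setting, most often with the mean in place of the median. With every library scaled to the same sum of FPKM, 59.1% of the genes 2-fold apart were higher in place of 47.9%.

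Without cysteine, division genes were again far lower than in complete medium, and ribosomal protein genes were lower. Genes of the antioxidant response, of iron handling, of the amino acid stress response, of p53 and of inflammation were higher. Of 30 mitosis genes 29 were at least 2-fold lower (median -3.10), with Birc5 27.2-fold lower, at 3.13 against 111 FPKM, and of 32 DNA replication genes 29 were lower (median -1.93), with Tk1 32.8-fold lower at 4.18 against 169 FPKM. Of 33 NRF2 and glutathione genes 9 were at least 2-fold higher and none lower, with a median of 0.68. Hmox1, the haem oxygenase gene, was 5.85-fold higher (319 against 53.8 FPKM, counting interval 5.02 to 7.10), and Slc7a11, which encodes the transport subunit of the cystine importer, was 2.59-fold higher (25.7 against 9.30 FPKM, counting interval 2.32 to 3.29). Fth1, which encodes the ferritin heavy chain, was at 19666 against 5606 FPKM.

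Further members of the antioxidant group were Gclm, a subunit gene of the enzyme that starts glutathione synthesis, at 34.3 against 12.4 FPKM, Sqstm1 at 147 against 35.8 and Gsta4 at 24.7 against 6.95. Nqo1 was at 156 against 79.5 FPKM, which is 1.95-fold higher. Of 19 iron and ferroptosis genes 6 were 2-fold higher and 1, Lpcat3, was lower (median 0.51), and Lpcat3 is named after its values were seen. This list is not separate from the others, since 8 of the 19 also belong to another list. Hmox1, Slc7a11 and Fth1 are members of the antioxidant list too. In every comparison 7 of the 23 p53, 5 of the 13 CDK inhibitor and 5 of the 17 ATF4 genes also belong to another list. Cdkn1a is on all 3 of these, so their results are not separate either. The iron exporter gene Slc40a1 was 5.92-fold higher, at 26.2 against 3.60 FPKM. Cth was 5.38-fold higher, at 17.2 against 2.39 FPKM (counting interval 3.52 to 17.8), in a group of 16 methionine cycle, transsulfuration and cysteine catabolism genes with a median of -0.48 in which Ahcy and the cysteine desulfurase gene Nfs1 were 2-fold lower.

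Of 23 p53 target genes 11 were at least 2-fold higher and none lower (median 0.77). Cdkn1a was at 127 against 32.1 FPKM, Mdm2, which encodes the ubiquitin ligase of p53, at 37.6 against 9.65, and Plk2 was 10.6-fold higher at 35.0 against 2.38 FPKM (counting interval 8.40 to 28.0). Of 13 CDK inhibitor and quiescence genes 6 were higher (median 0.69), including Klf6 at 59.2 against 10.9 FPKM and the p27 gene Cdkn1b at 28.0 against 11.5. Among 12 BCL2 family genes (median 0.51) 1 was 2-fold higher, Bbc3, which encodes PUMA, at 2.5 against 0.269 FPKM, and the survival gene Bcl2l1 was at 206 against 105 FPKM. Of 17 ATF4 and integrated stress response genes 8 were 2-fold higher and none lower (median 0.89), with Trib3 5.85-fold higher at 71.3 FPKM, Chac1 at 30.2, Cebpb at 13.6, Atf5 at 13.3 and Atf4 at 134 FPKM. Of 16 amino acid transporter genes 5 were 2-fold higher, the glycine transporter gene Slc6a9 among them, and 1, Slc43a1, was 6.0-fold lower (median 0.14).

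Of 20 NF-kB and inflammatory genes 11 were at least 2-fold higher and none lower (median 1.21). The chemokine gene Cxcl2 was at 145 against 22.5 FPKM, Il1b at 115 against 36.0, Ccl4 at 1183 against 295 and Ptgs2 at 50.5 against 12.1, and Csf2, which encodes GM-CSF, was listed at 0 in complete medium and at 12.3 FPKM without cysteine. Of 16 immediate early genes 2 were higher, Fosl2 and Jun (median 0.43), and of 26 autophagy and lysosome genes 3, Sqstm1, Map1lc3a and Ulk2 (median 0.28). Interferon response genes were not higher. Their median was -0.62, where random lists of equally abundant genes were at -0.26. Of the 27 genes 3 were 2-fold lower, with Cxcl10 at 55.4 against 160.0 FPKM, Oas3 at 14.8 against 42.0 and Isg20 at 70.2 against 143. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 were lower as well, H2-Aa at 7.17 against 27.5 FPKM, while the myeloid lysozyme gene Lyz2 was at 286 against 107 FPKM and the 7 macrophage and dendritic cell genes together had a median of -0.11 that turned above 0 under each of the other scalings. Of 12 neutrophil and monocyte genes 4 were 2-fold higher (median 0.35, inside the central 95%). Whether cells of these types carried any of the higher antioxidant, iron or inflammatory values in this library was not tested.

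Ribosomal, ribosome biogenesis and protein folding genes had lower medians without cysteine. Of 48 cytosolic ribosomal protein and elongation factor genes 12 were 2-fold lower and none higher (median -0.74, where random lists of equally abundant genes were at -0.47), with Rpsa 3.0-fold lower at 379 against 1139 FPKM, Rplp2 at 1291 against 2957 and the elongation factor gene Eef1a1 at 1473 against 2999.7 FPKM, although many ribosomal protein genes have processed copies that can share fragments. Of 30 ribosome biogenesis genes 6 were lower (median -0.64), among them Npm1 at 1215 against 3069 FPKM and Nolc1 at 35.7 against 86.1. Of 21 genes of the unfolded protein response 6 were lower and 1 higher (median -0.67), with the endoplasmic reticulum chaperone gene Hspa5 at 363 against 743 FPKM and Sdf2l1 at 10.8 against 44.8, and of 12 cytosolic heat shock genes 4 were lower (median -0.84), with Hspa8 at 2622 against 5269 FPKM. Atp5b and Ndufs2 were the 2 of 29 nuclear oxidative phosphorylation genes that were 2-fold lower (median -0.61). Random lists of equally abundant genes were also below 0. They were at -0.22 for ribosome biogenesis, -0.21 for the unfolded protein response, -0.28 for heat shock and -0.38 for oxidative phosphorylation. Of 10 histone genes 5 were lower and 1 was higher (median -1.24), again uncertain for shared sequence. Of the 9 with a known transcript length, only 2 had a counting interval below 1, and 1 had an interval above 1.

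Of 17 megakaryocyte genes 3 were 2-fold higher, including Plek at 135 against 35.9 FPKM, and 1, the integrin gene Itga2b, was 2.80-fold lower at 2.19 against 7.95 (median 0.45). The 38 stem cell genes had a median of 0.05, inside the central 95%, with Procr at 74.3 against 41.0 FPKM, Kit at 209 against 124, Mpl at 120.4 against 186 and Ctnnal1 3.53-fold lower. Cd34 was at 65.3 against 109 FPKM. Other medians inside the central 95% were -0.18 for amino acid synthesis genes driven by ATF4, -0.12 for tRNA synthetases, where the cysteinyl-tRNA synthetase gene Cars was at 75.7 against 61.8 FPKM, -0.08 for branched-chain amino acid catabolism, -0.15 for cholesterol and -0.24 for fatty acid synthesis, -0.64 for D-type cyclins and MYC, -0.28 for glycolysis and the hypoxia response, -0.18 for mTORC1 inputs, -0.42 for multipotent progenitor, 0.21 for erythroid and 0.07 for mast cell and basophil genes, and -0.19 for housekeeping genes. The list of D-type cyclins and MYC (percentile 3.72) moved outside the central 95% under 6 of the 15 alternatives. Myc was at 234 against 210 FPKM, Ccnd1 at 2.34 against 4.64, Actb at 14311 against 8607 and Gapdh at 607 against 1264. Among the genes with the highest ratios were the retinal reductase gene Dhrs3, 12.7-fold higher at 38.1 against 2.08 FPKM, the macrophage transcription factor gene Spic at 62.2 against 6.28 FPKM, Mgst2 at 19.6 against 1.24 and the galectin gene Lgals3 at 27.5 against 2.81.

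In total 1868 of the 10734 genes (17.4%) were at least 2-fold apart, 771 higher and 1097 lower without cysteine, and 105 and 240 were at least 4-fold higher and lower. Among the 6194 genes with a known transcript length 1089 were 2-fold apart, against 79.0 by counting error alone, and 20 of 36 lists lay outside the central 95% of random lists. The call for interferon genes ended with the mean in place of the median (-0.51) and in genes with at least 20 estimated fragments (-0.63), and those for the ribosomal protein, ribosome biogenesis, unfolded protein response, heat shock, oxidative phosphorylation, methionine cycle, BCL2 family, iron and megakaryocyte lists also ended under at least 1 other setting. With libraries scaled to the same sum of FPKM, 66.6% of the genes 2-fold apart were higher in place of 41.3%, and the medians shrank to -0.43 for ribosomal protein, -0.34 for ribosome biogenesis, -0.38 for unfolded protein response, -0.55 for heat shock, -0.30 for oxidative phosphorylation, -0.24 for methionine cycle and -0.32 for interferon genes.

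**Figure D1:**
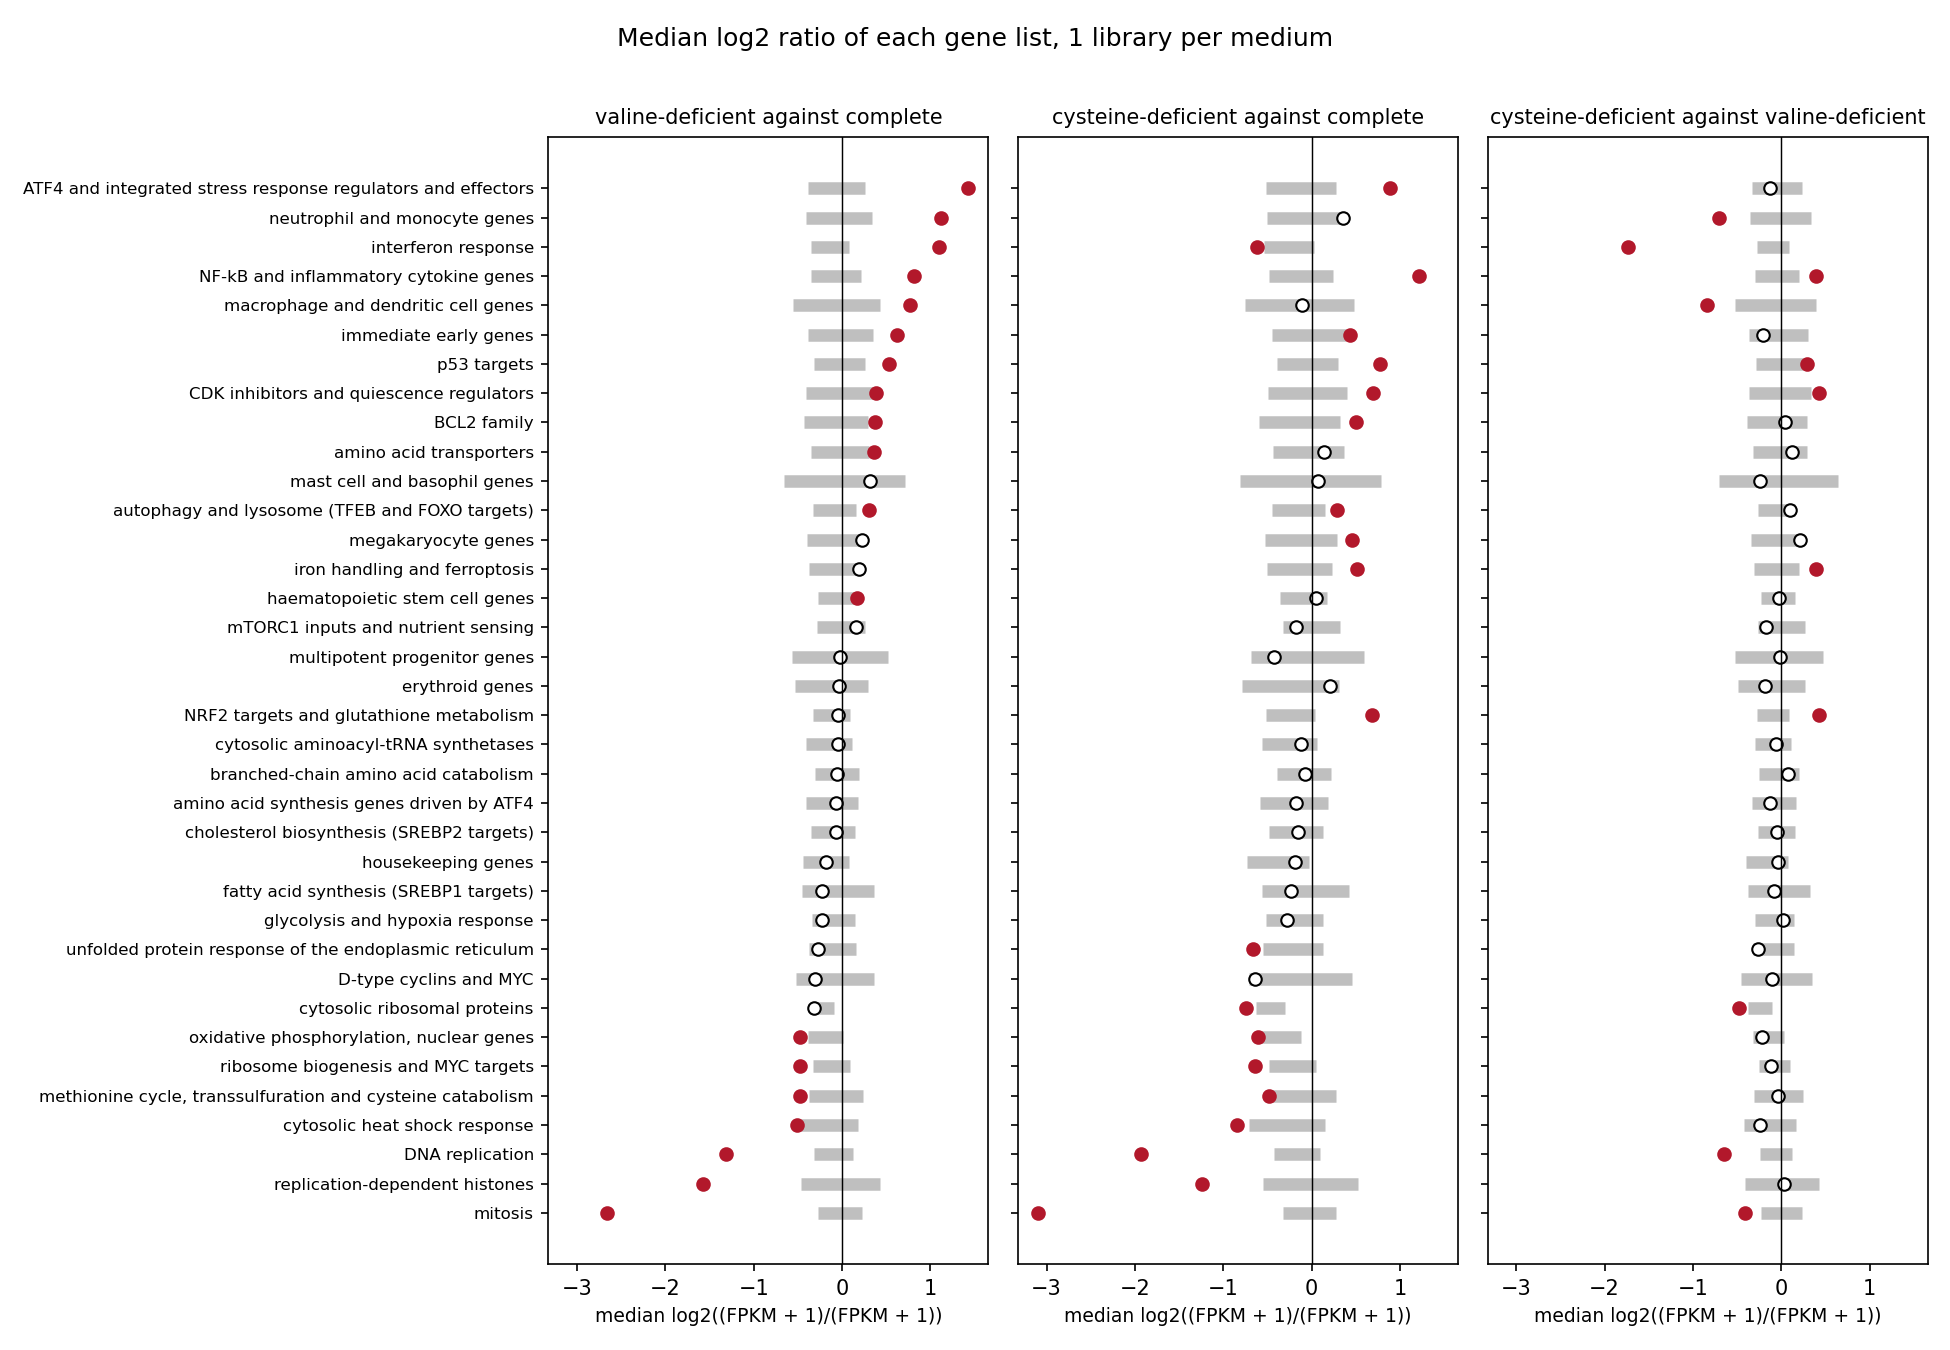
Median log2((FPKM + 1)/(FPKM + 1)) of each gene list (horizontal axis, log2 units) in each of the 3 comparisons. Filled red points are medians outside the central 95% of 10000 random lists matched on expression, open points are medians inside it, and grey bars span 2 SD on either side of the median of the random lists. Mitosis genes lie at -2.66 and -3.10 against complete medium, and interferon response genes at 1.10 without valine and -0.62 without cysteine.

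The cysteine-deficient and valine-deficient libraries, compared directly without the complete-medium library, stood farthest apart in the interferon response genes among the 36 lists. Of 27 such genes 24 were at least 2-fold lower without cysteine than without valine and none was higher, with a median of -1.74, and all 17 with a known transcript length had a counting interval below 1. Cxcl10 was 9.12-fold lower (55.4 against 513 FPKM, counting interval 0.0884 to 0.132), Ifit2 5.81-fold lower (10.3 against 64.7 FPKM) and Ifit3 4.79-fold lower (26.9 against 133 FPKM). Genes of other blood cells went both ways. H2-Aa was 9.18-fold lower (7.17 against 74.0 FPKM) and H2-Eb1 6.85-fold lower, the 7 macrophage and dendritic cell genes had a median of -0.84 and the 12 neutrophil and monocyte genes a median of -0.70, with 3 and 4 members 2-fold lower, but the 3 of the 7 that are not class II genes, Marco, Cd68 and Cx3cr1, were higher by less than 2-fold, and Lyz2 was 1.67-fold higher, at 286 against 171 FPKM. Cd68 is named after its values were seen.

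Antioxidant and iron genes were higher without cysteine than without valine. Of 33 NRF2 and glutathione genes 6 were 2-fold higher and none lower (median 0.43), with Nqo1, the quinone reductase gene, at 156 against 47.5 FPKM, Slc7a11 at 25.7 against 7.28, Gclm at 34.3 against 13.5, Hmox1 at 319 against 134 and Fth1 at 19666 against 8762. Of 19 iron and ferroptosis genes, 8 of which also belong to another list, 4 were higher and 2, Aifm2 and Lpcat3, were lower (median 0.40). Of 23 p53 target genes 3 were higher, Plk2, Gtse1 and Mdm2, and 1, Plk3, was lower (median 0.29), and the 13 CDK inhibitor and quiescence genes had a median of 0.42 with no member 2-fold apart. Of 20 NF-kB and inflammatory genes 6 were higher, among them Cxcl2 at 145 against 56.8 FPKM and Il1b at 115 against 45.9, while Csf1 and Ccl5 were lower (median 0.39). Tnfsf4, which encodes the OX40 ligand, was 3.56-fold higher at 41.0 against 10.8 FPKM.

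Division genes were lower still without cysteine. Of 32 DNA replication genes 8 were 2-fold lower and 1, Ccne1, was higher (median -0.65), with Mcm10 at 0.539 against 5.88 FPKM and Pola1, a subunit gene of DNA polymerase alpha, at 1.55 against 6.62. Of 30 mitosis genes 7 were lower (median -0.41), with the kinase gene Plk1 at 0.443 against 4.15 FPKM. Mcm10 and Plk1 rest on few fragments without cysteine, where a fragment on 1 kb is worth 0.450 FPKM. Among members of known length the counting interval was below 1 for 14 of 20 DNA replication genes but only 9 of 21 mitosis genes. None was above 1. The 48 cytosolic ribosomal protein genes had a median of -0.48, with Rpsa and Eef1a1 2-fold lower. Among stem cell genes Ly6a, which encodes Sca-1, was at 744 against 1718 FPKM and Mecom at 4.07 against 9.52, in a list whose median was -0.03. The ATF4 and integrated stress response genes had a median of -0.13, with Atf3 2.52-fold lower, and the other 24 lists inside the central 95% had medians from -0.26 for the unfolded protein response to 0.21 for megakaryocyte genes.

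In this comparison 1169 of 10734 genes (10.9%) were 2-fold apart, 443 higher and 726 lower without cysteine, and 651 of the 6194 with a known transcript length against 77.8 by counting error alone. Of 36 lists 11 lay outside the central 95%, and the NF-kB median turned to -0.02 in genes with at least 20 estimated fragments, while the calls for CDK inhibitor, iron, ribosomal protein, neutrophil and monocyte, and macrophage and dendritic cell genes ended under at least 1 other setting. With libraries scaled to the same sum of FPKM 52.8% of the genes 2-fold apart were higher in place of 37.9%. The median and the mean differed in sign in 3 lists per comparison, all inside the central 95%, and 27 of the 108 list medians of the 3 comparisons, none of them outside the central 95%, changed sign under another scaling.

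Some of the largest ratios belong to genes with near-identical copies and are uncertain. The alpha globin genes Hba-a1 and Hba-a2 were at 46.1 and 4.16 FPKM in complete medium, 0.201 and 58.2 without valine, and 99.2 and 46.7 without cysteine. Akr1b3 was at 106 FPKM in complete medium, 0.0098 without valine and 89.6 without cysteine, and the class I gene H2-Q9 at 95, 146 and 0.0981 FPKM. Rnaset2a, Dynlt1e, Tgtp1 and Rps27, which also have close copies, were likewise among the genes with the largest ratios.

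The ratios of the deficient libraries to the shared complete-medium library were correlated across genes, with Pearson's r of 0.612 and Spearman's rho of 0.606. Genes are not independent replicates, and 3 simulated unchanged libraries with a shared control gave 0.50 and 0.474. In that simulation every library had normal noise with the spread seen between the deficient libraries. This fixes the correlation near 0.50 and counts real differences between them as noise. Normal noise of that spread also puts more genes past 2-fold than the 10.9% seen between the deficient libraries. The simulated overlap counts are therefore too high to serve as a baseline. The covariance was 0.557 against 0.357 simulated, a difference of 0.20. Of the genes 2-fold higher or lower, 292 were higher in both deficient libraries (364 simulated, 45.2 for independent lists) and 423 were lower in both (362 simulated, 69.8 for independent lists), and how much of the excess over independent lists comes from the shared library is not known. Trib3, Cebpb, Chac1, Klf6, Hmox1 and Ccl4 were among the genes higher in both, and Tk1, Birc5, Ccnb1, Rrm2 and Mki67 among those lower in both. In opposite directions, 12 genes were higher without valine and lower without cysteine (27.9 simulated, 64.3 independent), among them Cxcl10, Isg20, H2-Aa, H2-Ab1, Cmpk2 and Apol9b, and 8 were lower without valine and higher without cysteine (27.7 simulated, 49.1 independent).

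**Figure D2:**
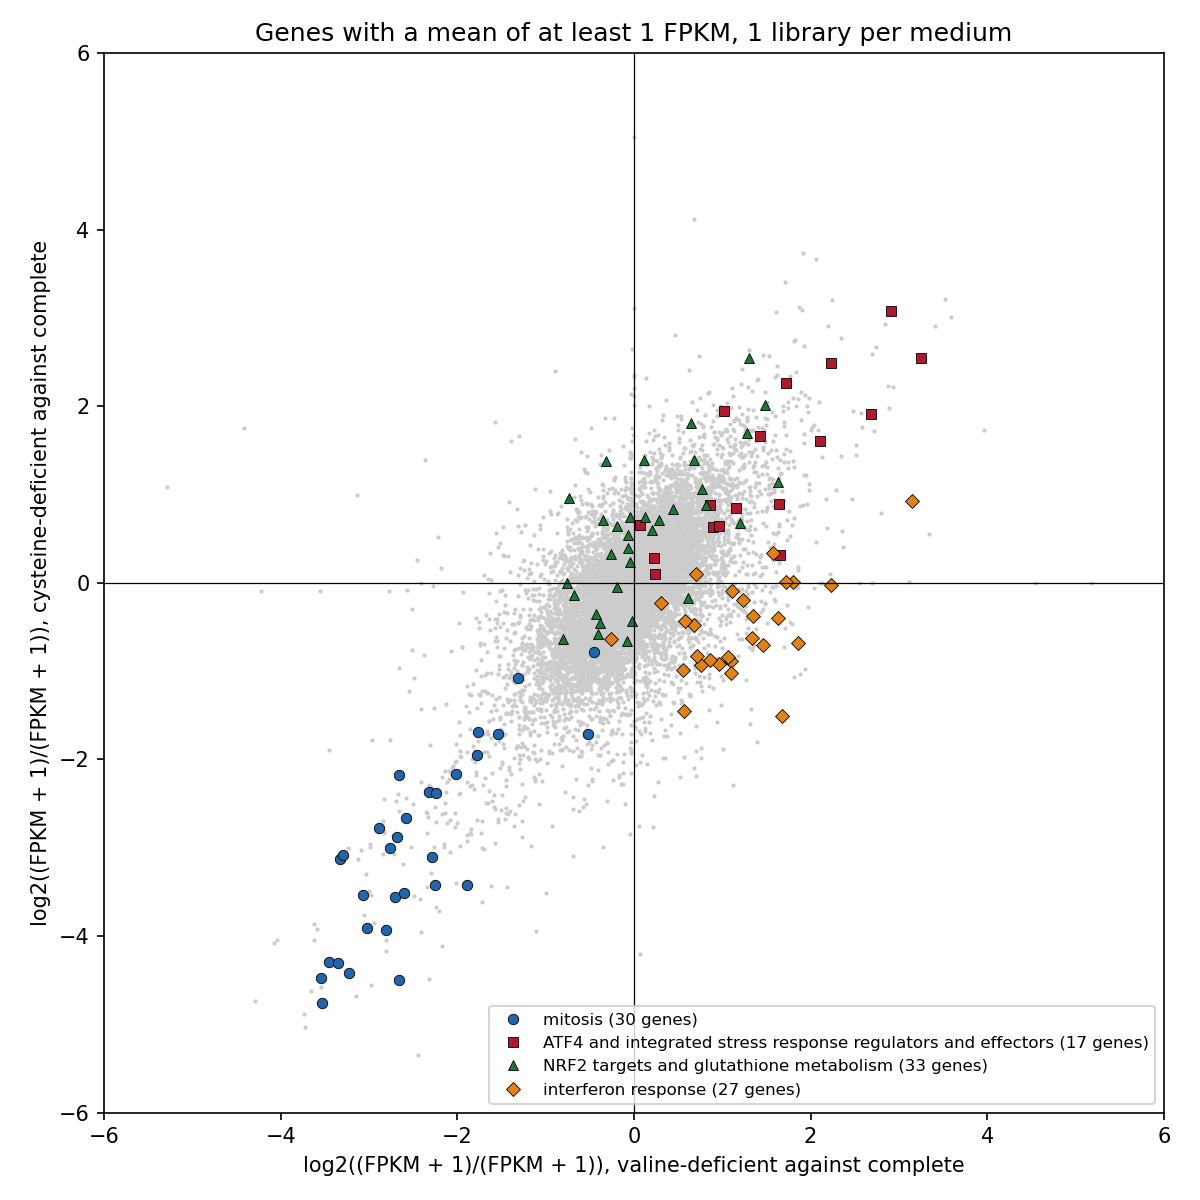
Log2((FPKM + 1)/(FPKM + 1)) of each of 10734 genes (grey points) without valine (horizontal axis) and without cysteine (vertical axis), each against the same complete-medium library, with members of 4 gene lists in colour. Axes end at 6 log2 units on either side of 0, which leaves 58 genes out of view. Mitosis genes lie low on both axes, ATF4 genes high on both, and interferon genes mostly right of 0 on the horizontal axis and mostly below 0 on the vertical axis.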

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

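The test on genes of other blood cells, 1 of the 4 other scalings (the same sum without small RNA genes) and the bounds set on the scaled medians were chosen after the result was seen. The other tests of this part were set out before their values were known, except for the limit on which small RNA ratios entered. The interferon response genes differed between the deficiencies in opposite directions from complete medium, with a median of 1.10 without valine and -0.62 without cysteine, and of -1.74 for cysteine-deficient against valine-deficient. The difference was not tested, since there is 1 library per medium, and the lower value without cysteine is the less firm side of it. Over all scalings the median stayed at 1.10 or above without valine and at about -1.57 or below for cysteine-deficient against valine-deficient, but without cysteine it shrank to -0.32.

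Counting error does not account for the difference between the deficient libraries, since the counting interval of the ratio of cysteine-deficient to valine-deficient excludes 1 in 100% of the 17 members of known length. Against complete medium 16 of the 17 intervals were above 1 without valine, but without cysteine 11 were below 1, 2 were above 1 and 4 included 1. More neutrophils, monocytes, macrophages or dendritic cells in the valine-deficient library could also carry the pattern if they passed the lineage-negative sort or arose in the 24 h of culture, and the 15 marker genes of these cells that are not class II genes had a median log2 ratio of -0.42 for cysteine-deficient to valine-deficient, with 9 below 0 (Ngp at -2.79, S100a8 at -1.21, Ly6c1 at -1.13) and 6 above 0. This stays open because the markers went both ways: the 4 class II genes, which interferon is known to induce, had a median of -2.83, while Marco, Lyz2, Lyz1 and Cd68 were higher without cysteine, at 0.84, 0.74, 0.62 and 0.32 (Cd68 is named after its values were seen). Of the 8 neutrophil and monocyte markers of known length only 3 had a counting interval that excluded 1, with 2 above it and 1 below it. A response to the missing amino acid is a candidate explanation that cannot be told apart from a difference between single cultures rather than media, with 1 library per medium.

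The second pattern is the low level of mitosis and DNA replication genes in both deficient libraries. Of their 41 members of known length 39 (95.1%) had counting intervals below 1 in both comparisons, which argues against counting error as the source. Over all scalings the medians of both lists stayed at about -1.18 or below in both deficient libraries, and both ratios use the same complete-medium library. A slowing of the cell cycle by either deficiency therefore stays a hypothesis, because it cannot be told apart from a difference between single cultures rather than media, with 1 library per medium.

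The third pattern is that small RNA genes differed by very large FPKM values between libraries, as Snora31 (named after its values were seen) with 162 FPKM in complete medium, listed at 0 without valine and at 452 without cysteine. Of the 82 small RNA genes that passed the filter, 56 were listed at 0 in at least 1 library. Ratios of small RNA genes between libraries were corrected for relative depth and compared with ratios of whole numbers up to 4. Only ratios within the span of those whole-number ratios entered, a limit that was not set out in advance. Of these 87 ratios 64.4% lay within 1% of a whole-number ratio, against 7.79% by chance and 11.6% among other genes. This is consistent with 1 or a few fragments on a very short transcript, each worth many FPKM. These genes make up 46, 51 and 54 of the genes 2-fold apart in the comparisons of valine-deficient with complete, cysteine-deficient with complete and cysteine-deficient with valine-deficient medium, and no biological explanation was tested for them.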

How the results depend on the processing

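The settings on small RNA genes, genes listed at 0 and estimated fragments were chosen after the data were seen. No paired analysis was possible because each medium has 1 library. Under the other settings the counts of genes 2-fold apart (1312 for valine-deficient and 1868 for cysteine-deficient against complete, 1169 for cysteine-deficient against valine-deficient) became 495, 739 and 337 with a pseudocount of 5, 750, 1082 and 573 at a mean of at least 5 FPKM, and 469, 691 and 345 in genes with at least 20 estimated fragments, where fewer genes enter. They were 3381, 4319 and 2981 at 1.5-fold, 226, 345 and 173 at 4-fold, and 1758 for cysteine-deficient against valine-deficient with a pseudocount of 0.1. The interferon median without cysteine, -0.62, went to -0.63 (percentile 2.65) in genes with at least 20 estimated fragments and to -0.51 (percentile 9.8) as a mean, which ended its call, and the NF-kB median for cysteine-deficient against valine-deficient reversed from 0.39 to -0.017 in genes with at least 20 estimated fragments. The cause was not tested in either. Lists outside the central 95% numbered 12, 12 and 7 with the mean in place of the median, and 7 for cysteine-deficient against valine-deficient in genes with at least 20 estimated fragments. In those genes the correlation across genes of the deficiency comparisons was 0.697. Scaling to the same sum moved the median log2 ratio of all genes from -0.04, -0.07 and -0.03 to 0.07, 0.19 and 0.12, and the share of 2-fold genes that were higher from 47.9%, 41.3% and 37.9% to 59.1%, 66.6% and 52.8%. Without small RNA genes that scaling gave 60.1%, 66.3% and 52.0%, and scaling to the same median gave 54.7%, 51.3% and 41.5%. Of 50 list medians outside the central 95% 26 stayed outside it in the same direction under every alternative that could be run for them, which were 15 for 22 of them and 14 for 4, and of 384 named gene comparisons at least 2-fold apart 234 stayed so under all scalings and pseudocounts and none reversed. Of the 58 list medians inside the central 95%, 47 stayed inside it under every alternative that could be run, and the rest moved outside it under at least 1. The megakaryocyte median for cysteine-deficient against valine-deficient moved outside it under 6 of 15. Depth limits low genes first, since a fragment on 1 kb is worth 0.481, 0.468 and 0.450 FPKM in the complete, valine-deficient and cysteine-deficient libraries.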

Other observations

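The gene families of this paragraph were searched for after the data were seen, among 257 families of symbols with at least 6 members, and are hypotheses at most. Outside the central 95% of 2000 random lists lay 45, 35 and 31 families in the comparisons of valine-deficient with complete, cysteine-deficient with complete and cysteine-deficient with valine-deficient medium. Families of unrelated genes would give 12.9, which does not measure chance between cultures, since family members can vary together. The guanylate-binding protein genes, interferon-induced GTPases, followed the interferon list, to which Gbp2 and Gbp3 belong, in 2 of the 3 comparisons. Of 11 measured members 9 were 2-fold higher without valine (median 1.71), with Gbp4 at 74.0 against 12.6 FPKM and Gbp2 at 367 against 118, and 10 were 2-fold lower without cysteine than without valine (median -1.67), but without cysteine they were not lower than in complete medium, with a median of -0.06, 1 member 2-fold higher and none lower. Nucleoporin genes were lower in both deficient libraries, with medians of -0.80 and -0.97 over 20 genes, and Nup155 was at 3.94 and 3.15 FPKM without valine and without cysteine against 12.7 in complete medium. Of the family medians given in this part only that of -0.06 changed sign under the other 4 scalings.

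Other families stood out without cysteine. Of 15 histone lysine demethylase genes of the Kdm family 7 were 2-fold higher than in complete medium and none lower (median 0.77), with Kdm6b at 26.3 against 8.50 FPKM and Kdm5b at 8.87 against 1.48. Of 10 C-type lectin genes 6 were higher (median 1.36), among them Clec4d, a myeloid receptor gene, at 57.2 against 15.2 FPKM and Clec4n at 11.7 against 1.01. Of 8 measured chemokine genes of the Cxcl family 6 were 2-fold higher and 1 lower without valine (median 1.35) and 5 higher and 2 lower without cysteine (median 1.79), with Cxcl16 higher in both, at 24.6 and 22.9 against 2.97 FPKM. Cxcl2 and Cxcl3, which encode neutrophil attractants, were at 145 and 22.5 FPKM without cysteine, 56.8 and 10.8 without valine and 22.5 and 4.42 in complete medium, while Cxcl5, another, was at 9.47 and 1.97 FPKM without cysteine and in complete medium and listed at 0 without valine. The interferon-induced Cxcl9 and Cxcl10 were highest without valine, at 25.5 and 513 FPKM, and lowest without cysteine, at 4.1 and 55.4, while Cxcl11, also induced by interferon, was at 16.4 without valine, 6.42 without cysteine and 4.14 in complete medium.

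Whether transcripts of proteins rich in the missing amino acid were lower was tested, by a prediction set out before the values were known, over 9015 genes with the longest open reading frame of the annotated transcript. Spearman's rho across genes of the protein's valine content with the log2 ratio of valine-deficient to cysteine-deficient was 0.010, and that of its cysteine content with the ratio of cysteine-deficient to valine-deficient was 0.005, ranks 13 and 12 of 20 amino acids from the lowest. Neither gave the negative value of at least 0.1 in size that the hypothesis predicted.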
